A study of Homo sapiens with 268 samples.

How the data were processed

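RNA sequencing of leukemic blasts from 268 patients was taken from 536 deposited files, 2 per library. Per the labels' protocols, blasts from cryopreserved samples were thawed and used for RNA extraction with Trizol without culture. Per the series design text, the source was blood or bone marrow; which of these applies to a given library is not given in the sources used here, nor is a sequencing batch. The authors aligned reads to hg38 and counted them per gene with featureCounts, per the series design text. That text names HISAT2 as aligner, while the submitters' processing notes list STAR; both are given here because they disagree. Versions, the annotation release and whether counting used strand are not given in the sources used here. The first kind of deposited file holds raw counts for 58395 Ensembl gene IDs. The second kind holds a normalized signal, which the authors made by dividing each count by a DESeq2 size factor, per the series design text. Size factors recomputed by median of ratios matched those deposited to a relative difference of at most 6.9e-05. The size factors ranged from 0.466 to 1.9.

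Groups were taken from the group label of each sample: 164 relapse and 104 maintained remission. Replicate numbers were given within each group and only name the libraries; they pair nothing. No files held identical counts. The most similar pair, relapse 13 and relapse 15, had a correlation of 0.989 and a chi-square of 16.9 per degree of freedom over 20489 genes. The next pair had 0.979 and 41.2. A chi-square above sampling noise argues against 1 library sequenced again, but cannot exclude 2 samples of 1 patient. Both libraries were kept, and without relapse 15 edgeR called 1675 genes. Gene names, types and coordinates came from GENCODE release 44 by Ensembl ID, for 57754 of the 58395 IDs; the other 641 held 0.56% of the counts. All 511 IDs on chromosome Y or belonging to the X-inactivation transcripts were left out of the tests.

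The main gene test was the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the raw counts with TMM factors and filterByExpr, which kept 22192 genes. No covariate was used. P-values were adjusted by Benjamini-Hochberg at 0.05, and a positive log2 fold change means higher in relapse. The standard error was the fold change divided by the square root of F. CPM values used TMM factors, and log2 CPM a prior count of 2. Scores of 38 gene lists, LSC17, principal components and library measures were compared by 2-sided permutation tests with 100000 resamples, whose smallest p is 1e-05. The adjustment covered all 38 lists; the result of 1 list is not reported here. Camera (limma 3.58.1) was run with a preset correlation of 0.01 and with an estimated one. The elastic net (glmnet 4.1.10, alpha 0.5) used 10 outer and 5 inner folds stratified by group. AUC intervals and the paired test are by DeLong's method (pROC 1.19.0.1).

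The gene lists, the tests and the rule for named genes were fixed before the data were examined. Named were the 8 highest and 8 lowest fold changes and the 6 smallest p in each direction among called protein-coding genes of at least 1 CPM whose medians differed the same way, up to 4 members of each list, and every LSC17 gene and AML marker that passed. The 12 higher and 6 lower genes of smallest rank-sum p were added after the data were seen.

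The gene tests were tried on simulated counts for relapse against maintained remission with 200 changed genes among 22192. At a log2 fold change of 1, edgeR recovered 93% and the rank-sum test 92%; at 0.5 they recovered 65% and 63%, with 4 and 8 false calls. At this depth and number of libraries smaller changes are often missed. Simulated counts hold no extreme libraries, so these shares do not cover genes led by a few libraries.

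Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, a rank-sum test, median-ratio size factors, limma-trend on the deposited normalized signal, no filter, a stricter filter, robust dispersion, and covariates for depth or for lineage scores. For the scores and models they were other normalizations, prior counts, summaries, gene numbers, penalties and folds. Added after the data were seen were fits without the 7 libraries of low similarity, without 1 of the most similar pair, with counts capped at the 95th percentile, with the small RNA share or the order of sample numbers as covariate, and without the library highest in a named gene. The groupings drawn at random numbered 44, and the elastic net was refitted on 40 permuted label sets. The p-values refer to differences between patients of this cohort. Those of edgeR are likely too small for some genes. In the random groupings edgeR called between 40 and 660 genes, while limma-voom and the rank-sum test called 0.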

Results

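Total RNA was sequenced from leukemic blasts of patients with cytogenetically normal acute myeloid leukemia (AML), a leukemia of immature myeloid cells in which the karyotype shows no abnormality. The blasts were collected before treatment, and all patients later reached a complete remission. The labels divide the 268 libraries, taken as 1 per patient, into 164 from patients who relapsed and 104 from patients whose remission was maintained. The total count per library ranged from 12495826 to 37333951, with a median of 18866316. A median of 33768.5 genes had at least 1 count. Total count, genes detected, the share of the 10 most abundant genes and the mitochondrially encoded share did not differ between the groups at the threshold (2-sided permutation tests, adjusted p from 0.824 to 0.913). Relapse libraries resembled the others less: their median correlation with all other libraries was 0.944 ± 0.00983 (SD, n = 164) against 0.947 ± 0.00602 (n = 104; permutation p = 0.00456, adjusted p = 0.0137 over 3 measures added after the data were seen). Below the lower fence of 0.928 for this measure lay 7 libraries, and all 7 were relapse libraries.

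The first comparison asked which genes differed before treatment between patients who later relapsed and those who did not. Several transcripts with known relations to AML subtype or outcome were higher in the blasts of relapsing patients (camera adjusted p = 0.00631 with an estimated correlation). Stem and progenitor genes were higher by list score. Camera called them with a preset correlation (adjusted p = 2.18e-08) but not with an estimated one (adjusted p = 0.0653). MIR155HG, the host transcript of the microRNA miR-155, had a median of 14.5 CPM in relapse and 8.33 CPM in maintained remission, with a log2 fold change of 2.08 (SE 0.23, edgeR quasi-likelihood adjusted p = 1.9e-12). Its 5 highest libraries, all from relapse, held 39.5% of its summed CPM, and its log2 fold change was 1.21 with capped counts and 0.95 by limma-voom, called in both. ALDH2, the mitochondrial aldehyde dehydrogenase, had medians of 5.75 and 2.15 CPM and a log2 fold change of 1.18 (SE 0.21, edgeR adjusted p = 1.68e-05). A relapse library exceeded a remission library in ALDH2 with a probability (area under the curve, AUC) of 0.702. Among the genes lower in relapse was TXNIP, a thioredoxin-binding regulator of glucose uptake, with medians of 947 and 1261 CPM and a log2 fold change of -0.46 (SE 0.12, edgeR adjusted p = 0.00611).

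Of 22192 genes tested, edgeR called 1625 at an adjusted p of at most 0.05, 1373 higher and 252 lower in relapse. They comprised 977 protein-coding genes, 455 long noncoding RNA genes and 193 of other types. The fold exceeded 2 for 276 of the higher and 38 of the lower genes. The rank-sum test, which a few extreme libraries cannot drive, called 209 genes (160 higher, 49 lower), and 194 of these were also called by edgeR. In 44 random regroupings of the libraries edgeR called a median of 103 genes, while the rank-sum test and limma-voom called 0 in each. Without the 7 libraries of low similarity edgeR called 947 genes (698 higher, 249 lower), so the higher calls fell in number and the lower ones hardly changed. With each gene's counts capped at its 95th percentile it called 441 (389 higher, 52 lower).

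**Figure D1:**
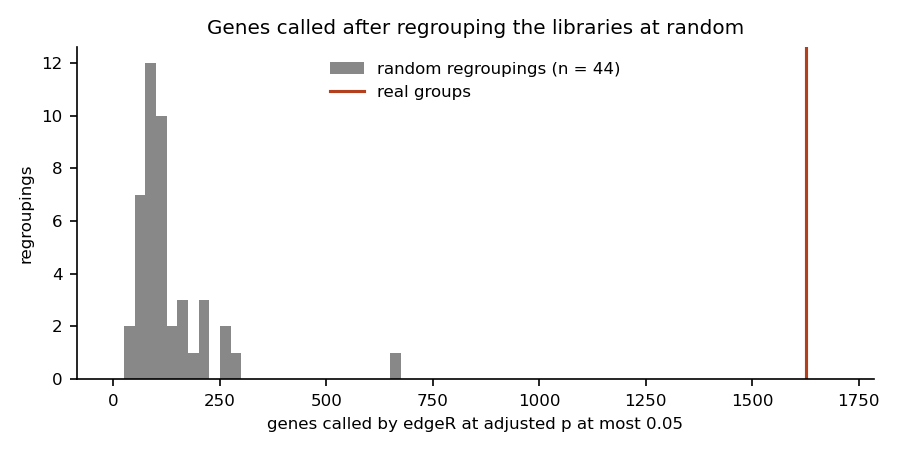
Number of genes called by edgeR (x axis) in 44 random regroupings of the 268 libraries into groups of the same sizes (grey; y axis, number of regroupings) and with the real groups (red line). The real groups gave 1625 genes and the regroupings between 40 and 660.

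The genes that best separated the groups by rank were chosen after their values were seen. The 12 protein-coding genes of smallest rank-sum p among those higher in relapse were ALDH2, EFNB1, LPAR1, FHL1, DEXI, ARHGEF17, TBC1D16, DOCK1, TMEM217, CD34, GRAMD1B and CALCRL. Their AUC lay between 0.669 and 0.702. EFNB1, which encodes the membrane ligand ephrin-B1, rose by a log2 fold change of 1.22 (SE 0.17, edgeR adjusted p = 6.86e-09). FHL1, a LIM-domain protein, had medians of 10.4 CPM in relapse and 4.95 CPM in maintained remission. CALCRL, the calcitonin receptor-like receptor, had medians of 9.81 and 3.74 CPM, and DOCK1, an activator of the small GTPase RAC, 13.1 and 2.45 CPM. CD34, the surface marker of hematopoietic stem and progenitor cells, had medians of 9.24 and 1.02 CPM (rank-sum adjusted p = 0.00429). It was not called by edgeR, where its log2 fold change was 0.59 (SE 0.37, adjusted p = 0.409). The means of CD34 were closer than its medians, at 51.2 CPM in relapse and 34.0 CPM in maintained remission. Its log2 CPM varied widely in both groups (SD 3.04 and 3.26). The 6 genes of smallest rank-sum p among those lower in relapse were GDE1, CCDC112, JMY, EIF5A2, RBPMS2 and ZNF211. Their log2 fold changes ranged from a value of -0.24 (SE 0.06) for ZNF211 to -0.98 (SE 0.22) for RBPMS2.

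**Figure D2:**
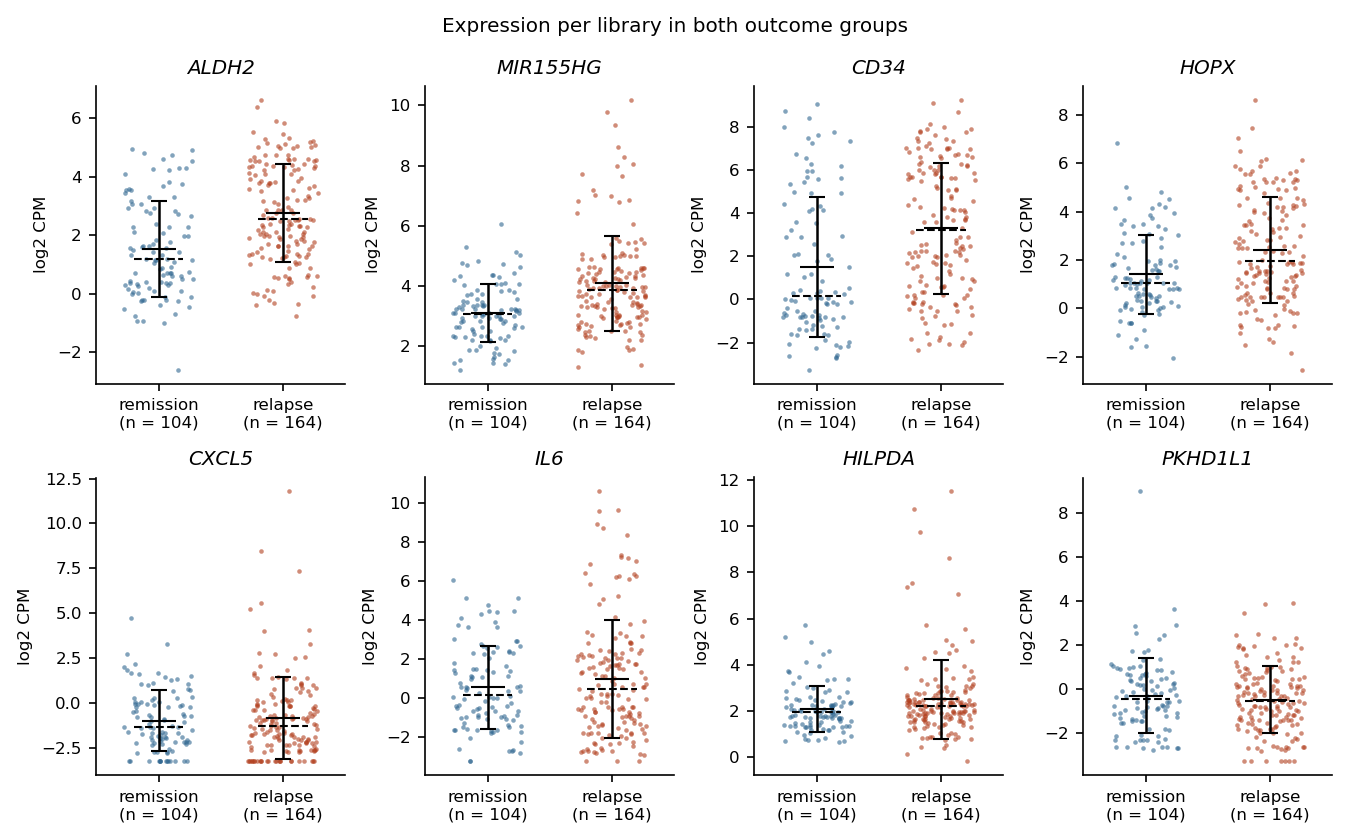
Expression in log2 CPM (y axis) of 8 genes in each library of the maintained remission (blue, n = 104) and relapse (red, n = 164) groups; the solid line and bars give mean ± SD and the dashed line the median. ALDH2, MIR155HG and HOPX are shifted across the relapse group, whereas CXCL5, IL6 and HILPDA are high in a few relapse libraries and PKHD1L1 in 1 maintained remission library. CD34 is spread widely in both groups, with low and high libraries in each and a higher median in relapse.

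ALDH2 (ENSG00000111275) lies on chromosome 12 at 111766887 to 111817532, MIR155HG (ENSG00000234883) on chromosome 21 at 25561810 to 25575168, EFNB1 (ENSG00000090776) on chromosome X at 68829021 to 68842160 and CD34 (ENSG00000174059) on chromosome 1 at 207880972 to 207911402 (hg38, whole gene spans in GENCODE release 44). Counts were taken per gene, so exons, introns and untranslated regions are not separated.

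Groups of genes were compared by a score per library, the mean z value of the log2 CPM of the genes of a list. Of 38 lists fixed before the data were examined, 4 were higher in relapse and none lower (2-sided permutation test, Benjamini-Hochberg adjusted over the lists). At an unadjusted p under 0.05 there were 7, and camera called 14 lists with a preset and 1 with an estimated correlation between genes. AML expression markers, a set of transcripts with known relations to AML subtype or outcome, scored 0.068 ± 0.29 (SD, n = 164) in relapse and -0.107 ± 0.254 (n = 104) in maintained remission, a difference of 0.175 z units (p = 1e-05, the smallest the permutations can give; adjusted p = 0.00038). Of its 30 measured members 11 rose and none fell over all genes tested, and 14 rose and 1 fell when adjusted over the list alone. The 11 were MIR155HG, SPARC, SETBP1, MN1, GAS6, BAALC, IL1RAP, IL3RA, BCL2, CD200 and FAM30A. MN1, a transcriptional coactivator, had medians of 5.52 CPM in relapse and 2.69 CPM in maintained remission. BAALC, a marker of immature blasts, rose by a log2 fold change of 1.29 (SE 0.30) and IL1RAP, a coreceptor of interleukin 1, by 0.40 (SE 0.10). SETBP1 had a lower median in relapse (2.92 against 3.35 CPM) although edgeR called it higher. BCL2 was not called without the library relapse 135 (edgeR adjusted p = 0.0875), nor CD200 without relapse 56 (edgeR adjusted p = 0.0571). BAALC was not called with capped counts (adjusted p = 0.0609), by rank sum (0.0507) or by limma-voom (0.0561), and IL1RAP not by rank sum (0.0565) or limma-voom (0.11). Camera kept this list with an estimated correlation (adjusted p = 0.00631), and 10 of its members rose without the 7 libraries of low similarity. With capped counts 5 of its members rose, and the rank-sum test called 3.

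Stem and progenitor genes were higher in relapse by 0.214 z units (permutation p = 0.00032, adjusted p = 0.00405; camera adjusted p = 0.0653 with an estimated correlation). Of 26 measured members 9 rose and none fell, and adjusted over the list alone 10 rose and 1 fell. Without the 7 libraries of low similarity 7 rose, with capped counts 5, and the rank-sum test called 6. HOPX, a homeodomain protein of quiescent stem cells, rose by a log2 fold change of 1.54 (SE 0.28) and PROCR, the endothelial protein C receptor, by 0.53 (SE 0.12). CRHBP, a binding protein of corticotropin-releasing hormone, rose by 2.37 (SE 0.31) with all libraries and by 0.84 without relapse 32, which held 1297 CPM, and it was not called with capped counts (adjusted p = 0.149) or by rank sum (0.26). Outside this list, DNTT, the DNA polymerase of immature lymphoid cells, rose by 3.48 (SE 0.48, edgeR adjusted p = 7.11e-09), with medians of 0.262 and 0.0593 CPM. Its 5 highest libraries, all from relapse, held 57.8% of its summed CPM. The log2 fold change of DNTT was 2.175 with capped counts and 1.784 by limma-voom, called in both. SDK2, a cell adhesion protein, rose by 2.22 (SE 0.29), although its medians were close (1.19 and 1.02 CPM) and the rank-sum test did not call it (adjusted p = 0.55).

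Dendritic cell genes were higher by 0.269 z units (permutation p = 5e-05, adjusted p = 0.00095; camera adjusted p = 0.06 with an estimated correlation). Of 13 measured members 10 rose, and 11 rose when adjusted over the list alone. Without the 7 libraries of low similarity 10 rose, with capped counts 6, and the rank-sum test called 2. NRP1, a coreceptor for semaphorins, rose by a log2 fold change of 1.91 (SE 0.30), and by 1.17 with capped counts and 1.2 with limma-voom. Its 5 highest libraries, all from relapse, held 35.2% of its summed CPM. AXL, a receptor tyrosine kinase for GAS6, rose by 1.59 (SE 0.23). The transcription factors BATF3 and IRF4 rose by 1.48 (SE 0.23) and 1.62 (SE 0.26). Without relapse 135 the log2 fold change of AXL was 0.98 and that of IRF4 0.99. By rank sum AXL, BATF3 and IRF4 were not called (adjusted p = 0.159, 0.146 and 0.466). The T cell score, in the same libraries, was lower in relapse by -0.24 z units at an unadjusted p of 0.011 (adjusted p = 0.0794), and CD247, a T cell receptor chain, had a log2 fold change of -0.41 (SE 0.16, edgeR adjusted p = 0.115). Without the 7 libraries of low similarity the T cell list passed the threshold as well.

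**Figure D3:**
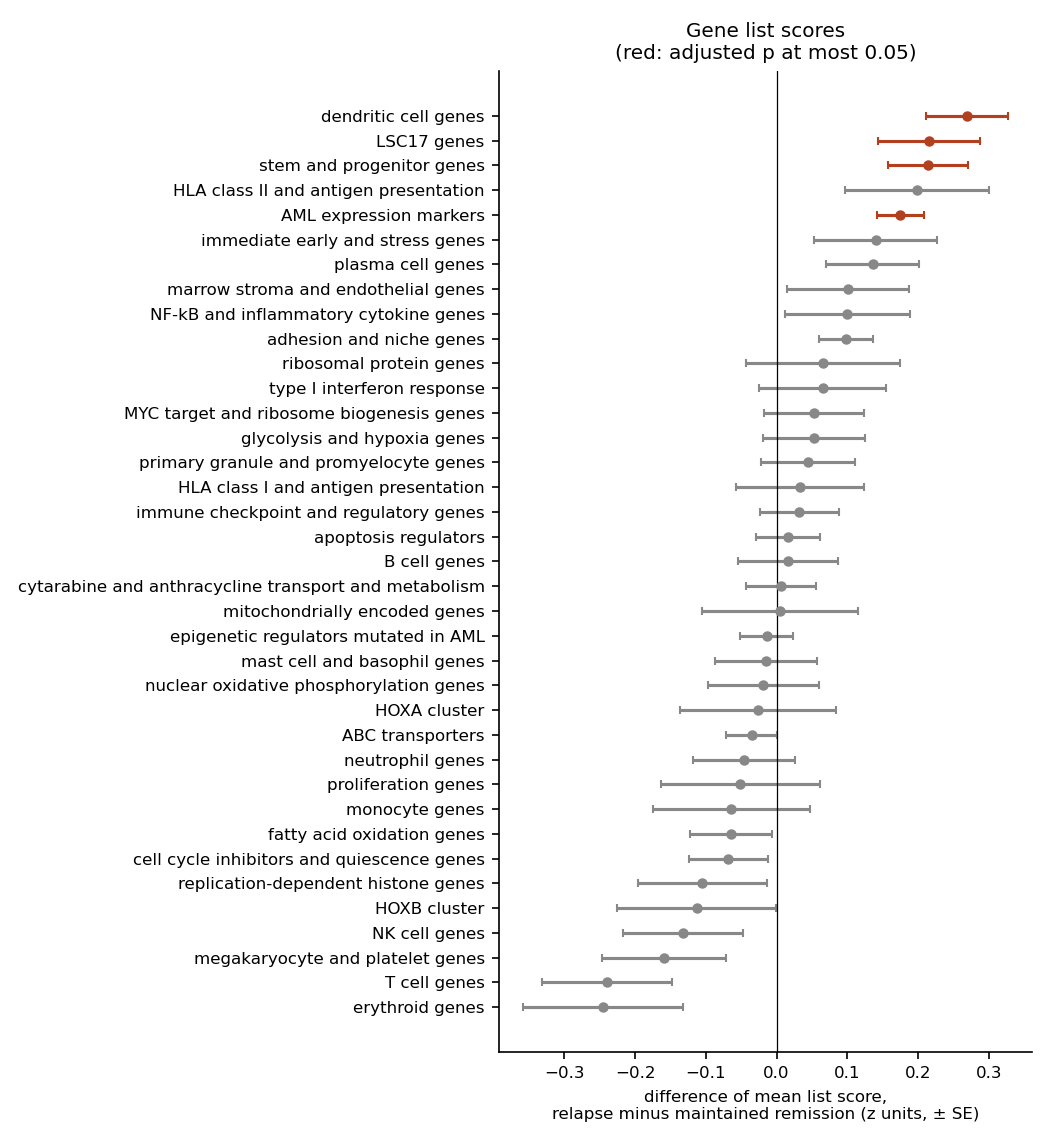
Difference of the mean list score between relapse (n = 164) and maintained remission (n = 104) in z units (x axis) for each of 37 gene lists (y axis); bars give the standard error of the difference, and red marks an adjusted permutation p of at most 0.05. The 4 red lists lie between 0.175 and 0.269.

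Several genes named by rule, most of them cytokines or chemokines, showed another form of difference, with high values in a few relapse libraries and close medians. CXCL5, a chemokine that attracts neutrophils, had the highest log2 fold change of all genes named by rule (4.59, SE 0.55, edgeR adjusted p = 2.1e-11), but medians of 0.31 and 0.287 CPM. The 5 highest libraries held 94% of its summed CPM, all 5 from relapse, and without relapse 147 its log2 fold change was 2.07. For IL6, CXCL1, CCL4L2, TNFSF15, HILPDA and HAMP, with log2 fold changes from 2.61 (SE 0.35) for CXCL1 to 3.07 (SE 0.45) for CCL4L2, the 5 highest libraries held between 62.5% and 77.7%. Without its highest library the log2 fold change was 2.23 for HILPDA (relapse 94), 2.35 for TNFSF15 (relapse 90) and 2.01 for CXCL1 (relapse 147). Without the 7 libraries of low similarity it was 4.62 for CXCL5, 2.02 for CXCL1, 1.88 for IL6, 1.22 for CCL4L2 and 0.67 for HILPDA, all still called, while TNFSF15 (0.63, edgeR adjusted p = 0.201) and HAMP (0.17, adjusted p = 0.616) were not. With capped counts IL6 alone of these 7 genes stayed called (1.23, edgeR adjusted p = 0.0295). HAMP, which encodes hepcidin, was not called without relapse 94 (edgeR adjusted p = 0.0609). CCL4L2 is a near-identical copy of CCL4, so reads may be divided between them and both values are uncertain. Of 26 NF-kB and inflammatory cytokine genes 17 rose and none fell (23 rose when adjusted over the list alone), among them CCL20, CCL4 and IL1A. Without relapse 90 the log2 fold change of CCL20 was 3.50 rather than 4.21 and that of IL1A 1.71 rather than 3.01. CCL20 was not called without the 7 libraries of low similarity (0.86, edgeR adjusted p = 0.135) or with capped counts (0.17, edgeR adjusted p = 0.876). However, the rank-sum test called 0 of them and the list score differed by 0.1 z units (permutation p = 0.306, AUC 0.499). With the 5 lineage scores as covariates the difference was 0.213 (permutation p = 0.00402, unadjusted, in a test that was not planned). In edgeR without the 7 libraries of low similarity 10 of the 17 were called, and with capped counts 6. The score difference was -0.189 z units among earlier-numbered samples (81 relapse, 53 maintained remission; permutation p = 0.106) and 0.389 among later-numbered ones (83 and 51; p = 0.0125).

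Other lists with called members had scores that did not pass. Of 27 immediate early and stress genes 11 rose (18 adjusted over the list alone), among them HSPA1A, an inducible heat shock protein with a near-identical copy, and the phosphatase DUSP2 (score adjusted p = 0.395). None of the 27 was called without the 7 libraries of low similarity, and none with capped counts. Of 36 type I interferon response genes 12 rose (24 rose and 1 fell when adjusted over the list alone), among them RIGI and IFITM3 (score adjusted p = 0.822), and the number was 21 without maintained remission 39 and 7 without relapse 153. It was 8 without the 7 libraries of low similarity and 1 with capped counts. Of 13 HLA class II genes 9 rose (12 adjusted over the list alone; reads of these similar genes may be misassigned), among them HLA-DQA1 and the transactivator CIITA (score adjusted p = 0.258), and 4 rose without relapse 90, 3 without the 7 libraries of low similarity and 3 with capped counts. Of 12 plasma cell genes 6 rose (6 adjusted over the list alone), including SLAMF7 and JCHAIN (score adjusted p = 0.237), and of 22 immune checkpoint genes 5 (6 adjusted over the list alone), including CD274, the gene of PD-L1 (score adjusted p = 0.827). Without the 7 libraries of low similarity 5 plasma cell and 4 checkpoint genes rose, and with capped counts 3 and 1. Of 28 glycolysis and hypoxia genes 7 rose (9 adjusted over the list alone), including LDHA and ADM (score adjusted p = 0.822), and 4 rose without relapse 94 or without relapse 87. None rose and 1 fell without the 7 libraries of low similarity, and none was called with capped counts. ADM was not called without relapse 94 (log2 fold change 0.75, edgeR adjusted p = 0.132). Of 18 primary granule genes 3 rose (3 adjusted over the list alone), including PRTN3 and ELANE (score adjusted p = 0.822), of which 3 rose without the 7 libraries of low similarity and none with capped counts.

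Some platelet, red cell and complement genes were called lower in relapse by edgeR, many of them through single libraries, and no list score was lower at the threshold. Of 18 megakaryocyte and platelet genes 11 fell (14 when adjusted over the list alone; score adjusted p = 0.237), but only 2 fell without maintained remission 82, and 1 fell and 1 rose with capped counts. That library held 510 CPM of PKHD1L1 and 969 CPM of the platelet integrin ITGB3. The log2 fold change of PKHD1L1 was -2.33 (SE 0.29) with it and 0.01 without it, and those of GP9, ITGB3, ITGA2B, PCSK6 and GNAZ were also no longer called without it (edgeR adjusted p from 0.109 to 0.522). CMTM5 was still called by edgeR, with a log2 fold change of -2.51 (SE 0.29) with it and -0.88 without it (edgeR adjusted p = 0.00916). It was not called with capped counts (adjusted p = 0.146), by rank sum (0.239) or by limma-voom (0.0661), and its 5 highest libraries held 60.6% of its summed CPM. Of 26 erythroid genes 7 fell (19 when adjusted over the list alone; score adjusted p = 0.146), and 2 fell without maintained remission 39 and none with capped counts. The fetal globin gene HBG2, which shares reads with the near-identical HBG1, had medians of 4.42 and 12.1 CPM, and HBD was not called without maintained remission 39 (edgeR adjusted p = 0.232). The complement genes C1QB and C1QC had log2 fold changes of -1.52 (SE 0.34) and -1.60 (SE 0.35), and C1QB was not called without maintained remission 30 (edgeR adjusted p = 0.0574), while C1QC was -1.02 without maintained remission 22. Neither was called with capped counts (adjusted p = 0.829 and 0.606) or by rank sum (0.784 and 0.829). Of 28 monocyte genes 2 fell, CD163 and FCGR3A, the latter a near-identical copy of FCGR3B and uncertain for that reason (1 rose and 2 fell when adjusted over the list alone; score adjusted p = 0.822), and CD163 was not called without maintained remission 22 (edgeR adjusted p = 0.0727). The collagen VI genes COL6A5 and COL6A6 had log2 fold changes of -1.55 (SE 0.29) and -1.24 (SE 0.18) by edgeR. COL6A5 was not called by rank sum (adjusted p = 0.0704), and COL6A6 neither by rank sum (0.21) nor with capped counts (0.137) or limma-voom (0.0753).

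No member passed in the lists of HOXA cluster, HOXB cluster, mast cell and basophil, proliferation, replication-dependent histone, HLA class I, mitochondrially encoded, ribosomal protein, fatty acid oxidation, cytarabine and anthracycline metabolism, or epigenetic regulator genes. Their score adjusted p lay between 0.669 and 0.962. The drug efflux gene ABCC4 was the 1 member of 15 ABC transporters that passed, with a log2 fold change of -0.42 (SE 0.12; 1 adjusted over the list alone, score adjusted p = 0.678), and it was not called with capped counts (adjusted p = 0.0734), by rank sum (0.205) or by limma-voom (0.181). Of 23 adhesion and niche genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; score adjusted p = 0.0794), and 1 rose without relapse 90, without the 7 libraries of low similarity or with capped counts. Of 18 B cell genes 4 rose, DNTT among them (6 adjusted over the list alone; score adjusted p = 0.881), and of 18 marrow stroma and endothelial genes 2 rose and 1 fell (9 and 1 adjusted over the list alone; score adjusted p = 0.669). Without maintained remission 15 the stroma genes that rose were 5, and without maintained remission 76 they were 4. Of 16 neutrophil genes 1 rose and 1 fell (the same adjusted over the list alone; score adjusted p = 0.822), of 21 NK cell genes 1 fell (1 adjusted over the list alone; score adjusted p = 0.395), and of 30 MYC target genes 2 rose (2 adjusted over the list alone; score adjusted p = 0.822). Of 44 nuclear oxidative phosphorylation genes 1 fell and none when adjusted over the list alone (score adjusted p = 0.881). Of 27 apoptosis regulators BCL2 alone rose (1 adjusted over the list alone; score adjusted p = 0.881), and of 18 quiescence genes 1 rose and TXNIP fell (the same adjusted over the list alone; score adjusted p = 0.669). CCR7, the 1 T cell gene called higher, had a lower median in relapse (5.57 against 7.01 CPM) and was not called without relapse 120 (edgeR adjusted p = 0.116).

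The second comparison applied LSC17, a weighted score of 17 genes built by others on leukemic stem cells, to these libraries. It was higher in relapse, at 0.094 ± 0.279 (SD, n = 164) against -0.0452 ± 0.205 (n = 104), a difference of 0.139 or 0.55 pooled SD (2-sided permutation p = 2e-05). Its AUC was 0.653 (95% DeLong interval 0.588 to 0.718). Of the 17 genes, SOCS2, a suppressor of cytokine signaling, and FAM30A, a noncoding RNA gene, passed over all genes, both higher, and 6 rose when adjusted over the list alone. SOCS2 rose by a log2 fold change of 1.24 (SE 0.24) and FAM30A by 0.69 (SE 0.21). By rank sum neither was called (adjusted p = 0.0702 and 0.132), and with capped counts FAM30A was not (0.145). The rank-sum test called 2 others of the 17 genes. With capped counts edgeR called 2 higher, SOCS2 among them. The unweighted list score of the same genes was higher by 0.215 z units (permutation adjusted p = 0.0295; camera adjusted p = 0.23 with an estimated correlation).

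The third comparison asked how well expression separated the groups in libraries not used for fitting, since the series title names prediction of relapse. An elastic net on the 5000 most variable genes gave an out-of-fold AUC of 0.744 (95% DeLong interval 0.685 to 0.803). With the fitted scores held fixed, the permutation p was 1e-05, the smallest the permutations can give. The DeLong results here also hold the scores fixed and leave out the spread from refitting. In 40 refits on permuted labels the highest AUC was 0.574. The elastic net kept a median of 58.5 genes per fold. The AUC exceeded that of LSC17 in the same libraries by 0.0906 (95% interval 0.0216 to 0.16, paired 2-sided DeLong test p = 0.0101, a test added after the data were seen). LSC17 was fixed on other patients, whereas the elastic net was fitted within this cohort.

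**Figure D4:**
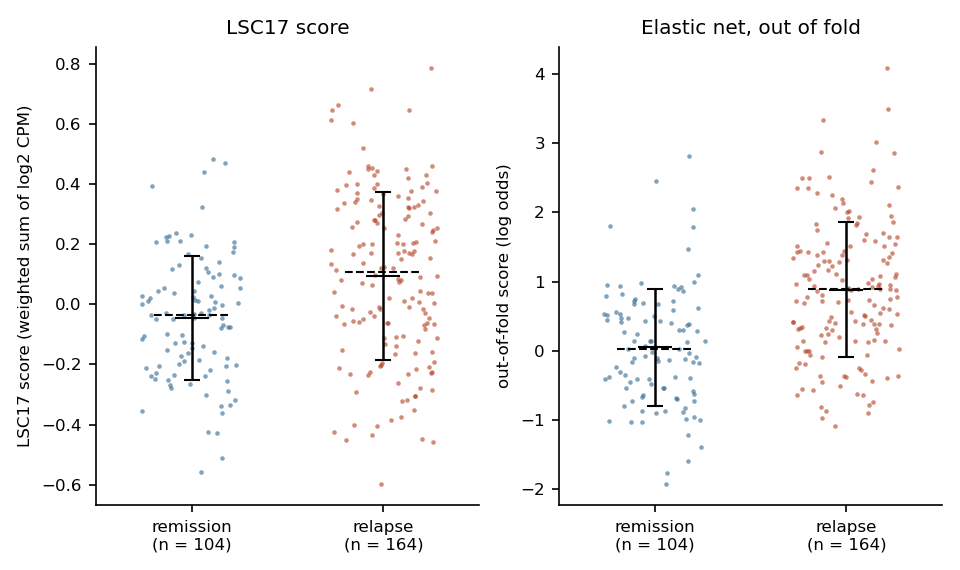
LSC17 score (left, weighted sum of log2 CPM) and out-of-fold elastic net score (right, log odds) of each library in maintained remission (blue, n = 104) and relapse (red, n = 164); the solid line and bars give mean ± SD and the dashed line the median. The groups overlap in both scores, with an AUC of 0.653 for LSC17 and 0.744 for the elastic net.

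The main axes of variation between patients were compared last. The first principal component of the 2000 most variable genes held 25.6% of the variance and the second 12.2%, and neither differed between the groups (difference -0.0302 and 0.0619 SD, permutation adjusted p = 0.992 and 0.936). Component 6 (2.9% of the variance), with CD34, MRC1, AIF1L, DOCK1 and BAALC at its negative end and the erythroid genes AHSP and ALAS2 at its positive end, differed by -0.774 SD, toward the CD34 end in relapse (permutation adjusted p = 1e-04). Component 9 (1.63%) differed by 0.408 SD (permutation adjusted p = 0.0059), with MRC1 and SOCS2 at its positive end and ELANE and MMP8 at its negative end.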

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

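The tests with capped counts, of the relations between list scores and of random regroupings were chosen after the results were seen. The 5 lineage scores were those of the T cell, B cell, erythroid, megakaryocyte and platelet, and monocyte lists. Planned with these as covariates were the count of called NF-kB genes and the stem and progenitor score difference. The NF-kB score difference with these covariates was not planned, and its p is unadjusted.

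Of 26 NF-kB and inflammatory cytokine genes edgeR called 17 higher in relapse. The rank-sum test called 0 of them, and the list score did not differ at the threshold (0.1 z units, permutation p = 0.306). With the 5 lineage scores as covariates 16 of the 17 called genes stayed called and higher. This argues against a different share of these lineages, monocytes among them, as the whole cause, as far as expression scores measure it. The NF-kB and monocyte scores had a rho of 0.62 within relapse and 0.641 within maintained remission. However, the monocyte score was not higher in relapse (difference -0.064 z units, permutation p = 0.557). With the 5 lineage scores as covariates the NF-kB score difference grew from 0.1 to 0.213 z units (permutation p = 0.00402). These values argue against a larger share of monocytes in relapse as its source. A part played by monocytes in single libraries was not tested. A few relapse libraries with extreme values could account for most of the calls, as 6 of the 17 stayed called with capped counts. Stress or activation of the cells before RNA extraction stays open. The NF-kB and stress scores had a rho of 0.752 within relapse and 0.774 within maintained remission. A relation present in both groups does not by itself give a difference between them. The stress score difference was 0.14 z units (permutation p = 0.125, adjusted p = 0.395). The same relation would follow if some leukemias were inflamed in the patient, which the labels do not separate.

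Stem and progenitor genes were also higher in relapse by list score. Camera called them with a preset correlation (adjusted p = 2.18e-08) but not with an estimated one (adjusted p = 0.0653). With the lineage scores as covariates 91.2% of the stem and progenitor score difference was kept (permutation p = 1e-04). This argues against fewer cells of the 5 scored lineages as the whole cause, as far as expression scores measure them. Other cell types were not among the covariates and no blast percentage was used, so a different share of blasts stays open. A few relapse libraries with extreme values are argued against as well, since 5 of the 9 called members stayed called with capped counts and the median of the list genes differed (permutation p = 0.00042). A more primitive state of the blasts in patients who relapse remains a hypothesis, found and tested on the same libraries; blood against marrow origin, mutations and sequencing batch stay open as untested.

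Chance is argued against as the whole source of the gene counts and of the elastic net AUC. With 44 regroupings and 40 refits it cannot be excluded, and the regroupings bear on the totals, not on single genes. Only the real grouping, 1 of 45, gave 1625 genes by edgeR, with 660 the highest of the others. The same held for limma-voom (1 of 45; 179 against 0) and the rank-sum test (1 of 45; 209 against 0). The elastic net AUC of 0.744 was reached in 1 of 41 label arrangements, the real one, and the highest other was 0.574. Since random groupings gave a median of 103 genes by edgeR, some of its 1625 calls are likely to be false.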

How the results depend on the processing

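Tests without the 7 libraries of low similarity, with capped counts, with the small RNA share or sample numbering as covariate, without 1 of the most similar pair and without single libraries were chosen after the data were seen. The count of 1625 genes moved to 209 with the rank-sum test, 179 with limma-voom, 235 with limma-trend on the deposited normalized signal, 3372 with no filter, 947 without the 7 libraries and 441 with capped counts. No filter tested more genes (56040); for the other settings the cause was not tested. The 40 refits without a single library called between 1402 and 1680 genes. Camera called 14 lists with a preset and 1 with an estimated correlation, against 4 by score. The camera runs differed only in that correlation, so its choice alone moved the count from 14 to 1. The preset was 0.01, and the estimate was 0.76 for the erythroid and 0.547 for the T cell list, which lost their calls. For the AML expression markers, which kept theirs, it was 0.047. Why camera and the score test differed was not tested. With the median of the list genes 3 were called (the LSC17 list lost its call) and without the 7 libraries 5 (the T cell list gained one); the cause was not tested. LSC17, the elastic net (AUC 0.725 to 0.769) and the library measures (0 of 4) kept their calls in each alternative run. Of 10 principal components 2 were called in each run, but component 9 was not called with 500 genes (adjusted p = 0.868) or all genes (0.0814), where components 4 and 10 were; components were not matched between runs and the cause was not tested. By rank sum the AUC was below 0.5 for CXCL5 (0.491), CCL4L2 (0.497), CCL20 (0.48), CCL4 (0.486) and CCR7 (0.466). CCR7 also reversed with limma-voom (-0.084) and limma-trend (-0.058), and ADM without the 7 libraries (-0.095). PKHD1L1 reversed with DESeq2 (0.016), without maintained remission 82 (0.012) and with lineage scores as covariates (0.193), as did GP9 (0.024), ITGB3 (0.157) and PCSK6 (0.108) with those covariates; apart from the single library, the cause was not tested. Of the 79 named genes called, 24 kept their direction and call in every setting that tested them. Among the 24 were MIR155HG, DNTT, HOPX, MN1 and TXNIP. The rank-sum test was 1 of these settings. Most of the 24, such as ALDH2 and EFNB1, were named for a small rank-sum p, so their call by that test was fixed in advance. Leaving out libraries under 0.5 of the median total removed none, so it gave no value. No paired analysis was possible because the sample numbers do not link relapse to maintained remission patients. Small changes were often missed, as edgeR recovered 65% of simulated ones at a log2 fold of 0.5 with 268 libraries. Depth and patient number were not varied, so the cause was not tested.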

Other observations

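All tests in this part were chosen after the results were seen. The inflammatory and stress programs moved together across patients of both groups. The NF-kB list score correlated with the immediate early and stress score within relapse (r = 0.752, rho = 0.752, n = 164) and within maintained remission (r = 0.765, rho = 0.774, n = 104), and with the glycolysis and hypoxia score (r = 0.743 and 0.602, rho = 0.737 and 0.6). Each had a permutation p of 1e-05, the smallest the permutations can give, and an adjusted p of 1.43e-05 over 10 relations. Without the 2 libraries farthest from the median score these r were 0.722, 0.769, 0.699 and 0.616. With the stem and progenitor score the relation was negative (r = -0.271 in relapse, p = 0.00034; r = -0.47 in maintained remission). The lists in each of these pairs share 0 genes.

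Part of the called genes were led by few patients: in 375 of 1625 the 5 highest libraries held over 25% of the summed CPM. The library relapse 135 was among the 5 highest for 501 of the 1373 genes higher in relapse, relapse 94 for 461 and relapse 90 for 453, and these 3 are among the 7 of low similarity. The 5 highest libraries held a median of 14% of the summed CPM of genes called by edgeR, 8.9% of those called by rank sum and 5.7% of all tested genes.

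In 10 random divisions of the patients into 2 sets, edgeR called a median of 658 genes in the first set (240 to 1072). Of these a median of 46.6% had the same direction and an unadjusted p under 0.05 in the other set, and 85.7% had the same direction. The rank-sum test called a median of 2.5 genes in the first set (0 to 84), and in the largest case 14 of the 84 followed in the other set.

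The order of the sample numbers, whose meaning the labels do not give, mattered for 1 of 6 lists examined. The NF-kB score difference changed between earlier and later numbers (-0.189 and 0.389; permutation of the order within groups, p = 0.00099, adjusted p = 0.00594). For the stem and progenitor list the differences were 0.266 (p = 0.0021) and 0.159 (p = 0.0522; p of the change 0.348), so this list did not pass among later numbers. For the AML expression markers they were 0.226 (p = 1e-05, the smallest the permutations can give) and 0.121 (p = 0.0141; p of the change 0.118, adjusted p = 0.141). For the LSC17 genes they were 0.33 (p = 0.001) and 0.0929 (p = 0.372; p of the change 0.1, adjusted p = 0.141), and for the dendritic cell genes 0.175 (p = 0.0318) and 0.362 (p = 0.00056; p of the change 0.105, adjusted p = 0.141). For the T cell genes they were -0.439 (p = 0.0012) and -0.041 (p = 0.75; p of the change 0.0304, adjusted p = 0.0913).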
